A study of Mus musculus with 2 samples.

How the data were processed

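The data are 2 single-cell RNA sequencing libraries of CD4+ T cells taken from the spinal cord of C57BL/6 mice (the central nervous system in other label fields) at day 15 after immunisation with the MOG(35-55) peptide, 1 from WT mice and 1 from Tnfr2-/- mice. The peptide comes from a myelin protein. Immunisation with it, with pertussis toxin given as well, is used to start experimental autoimmune encephalomyelitis, a mouse model of inflammation of the central nervous system. The cells were sorted by flow cytometry and put through the 10x Chromium 3' v3 chemistry, per the labels. Nothing in the labels says how many mice went into each library.

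The authors deposited raw UMI counts per gene and cell barcode, 1 matrix per library, already reduced to barcodes called as cells. The counts were made with Cell Ranger 3.1.0 against mm10, per the submitters' processing notes. The annotation version and the settings of cell calling are not given in the sources used here. Both matrices list the same 31053 features. The deposited matrices hold 6961 barcodes and 60853362 UMIs for WT, and 8032 barcodes and 64325443 UMIs for Tnfr2-/-. Median depth was 6677 and 5865 UMIs per barcode.

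From there, barcodes with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its automatic threshold marked 1 WT and 4 Tnfr2-/- barcodes, too few for it to have worked. The highest-scoring barcodes were removed instead, at a rate of 0.8% per 1000 barcodes, which took out 341 and 451. The remaining 5787 and 6570 cells were clustered together on 30 principal components of 2000 variable genes. TCR and immunoglobulin variable segments, ribosomal, mitochondrial and sex-linked genes and Tnfrsf1b were left out of that step. The graph joined 15 nearest neighbours and was split with the Leiden method at resolution 1 (leidenalg 0.10.2).

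A cluster was called X-like where at least 3 markers of class X were among its 20 leading genes by fold and that class had more markers among the top 10 than any other. Leading genes had to be detected in 25% of the cluster's cells, and classes other than CD4 T cells also needed a lineage gene among them. The markers were fixed in advance and this scoring rule was not. Its last condition, that the 2 leading genes may not both be markers of other classes only, was added after the clusters were seen. Clusters with a Cd3e UMI in at least 50% of cells that were not named after another lineage were taken as T cells. Of 19 clusters, 12 were T cell clusters.

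UMIs were summed over the T cells of each library and given as CPM, UMIs scaled to the same total in both libraries, with exact Poisson 95% intervals. Ratios are log2 of Tnfr2-/- over WT with exact conditional binomial intervals. Shares of cells have exact Clopper-Pearson intervals. All of these intervals cover counting error only. With 1 library per group no test was possible and no p-value is given. For shares of cells with a UMI, each cell was thinned to 2000 UMIs, which left out 92 WT and 163 Tnfr2-/- T cells.

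Gene lists were fixed before the data were examined, as were the marker lists of other cell types. They covered the Th17, Th1, Th2, Tfh and Treg programmes, pathogenic cytokines, and naive and central memory genes. They also covered NF-kappaB, the TNF superfamily, T cell activation, inhibitory receptors, cell cycle, interferon response, adhesion and migration, apoptosis and cytotoxic granules. The others were glycolysis, oxidative phosphorylation, MHC class I, immediate early and heat shock genes, mitochondrially encoded genes, haemoglobin, sex-linked and ribosomal protein genes. A list's median log2 ratio over members with at least 5 CPM in either library was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list is called apart below the 2.5th or above the 97.5th percentile. These percentiles describe these 2 libraries.

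The genes named in the text were set by rule. They are 12 genes named in advance, the 12 highest and 12 lowest ratios in T cells among genes with at least 20 CPM in 1 library, and the 5 highest and 5 lowest within Treg-like and other T cells at 50 CPM. Predicted models, mitochondrial, ribosomal, histone, TCR, immunoglobulin and sex-linked genes and markers of other cell types were left out of the ranking. For each list, the highest, lowest and most abundant members are named. Some genes that these rules name are not reported here.

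The statistics were first tested on simulated data drawn from the real T cell means and library sizes, with 200 of 4999 genes altered. The 50 genes altered at each of 1.25-, 1.5-, 2- and 4-fold had an interval on the right side of 0 in 100% of cases, while 4.61% of the 4799 unaltered genes had one that left out 0. In the list step, which ran on 8425 genes, 4.75% of 400 random lists of 15 unaltered genes were called apart. The simulation holds counting error, with UMIs drawn independently, and no variation between mice or between cells. In the data 5 cells could hold much of a gene's UMIs, such as 70.4% for Il2 in WT. For such genes the intervals understate the spread even within a library, and the simulated rates need not hold.

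Coordinates are from GENCODE M21 on GRCm38, the build that mm10 names, matched by Ensembl identifier for 8510 of 8515 measured genes. Alternatives covered the cell filter, doublets, scaling (including edgeR 4.0.16 TMM factors), cell weighting, the choice of T cells, equal cluster composition, resolution, centring genes within libraries, the CPM minimum and the thinning depth. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and R 4.3.3 were used.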

Results

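CD4+ T cells that had entered the spinal cord were compared between WT mice and mice lacking TNFR2, the receptor for TNF that is encoded by Tnfrsf1b. The question set by the series is which genes differ between the 2 genotypes in these infiltrating cells. There was 1 library per genotype, so no value has a replicate. After filtering, 5501 WT and 5976 Tnfr2-/- cells fell in T cell clusters, with 49393977 and 48360422 UMIs. Median depth was 6999 UMIs per T cell in the WT library and 6044 in the Tnfr2-/- library. T cells were 95.1% and 91.0% of the cells clustered. Over the 8515 genes with at least 5 CPM in either library the median log2 ratio, Tnfr2-/- over WT, was 0.03.

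Tnfrsf1b (ENSMUSG00000028599; chromosome 4, 145213463 to 145246870, minus strand) was detected in both libraries. Its level in T cells was 67.6 CPM in WT (95% interval 65.3 to 69.9) and 11.7 CPM in Tnfr2-/- (10.7 to 12.7), a log2 ratio of -2.54 (-2.67 to -2.41). In WT, Treg-like cells held the highest level of any T cell cluster, 147.5 CPM, against 20.1 CPM in the Tnfr2-/- library. Naive-like cells held 28.1 and 4.95 CPM. The counts are 3' tags and the deleted part of the gene is not given in the sources used here, so residual tags do not tell whether a functional transcript remained, and tags outside the deleted part check nothing. Tnfrsf1a, which encodes the other TNF receptor, was at 20.7 and 20.4 CPM (log2 -0.02, or 0.22 over all cells sorted).

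The largest group difference lay in genes of naive and central memory T cells, which were higher in the Tnfr2-/- library. All 10 measured members had a ratio above 0, and 6 were at least 1.5-fold higher. The median log2 ratio was 0.77, above all 10000 random lists (middle 95% -0.09 to 0.12). Bach2, a repressor of effector differentiation, was at 3.56 CPM in WT and 8.89 CPM in Tnfr2-/- (log2 1.32). The interleukin-7 receptor gene Il7r, the most abundant member, was at 265.7 and 401.1 CPM, and Satb1 had the lowest ratio, 0.27. Among the 12 genes with the highest ratios were Tcf7, a transcription factor of naive and memory T cells, at 35.0 and 86.3 CPM, and S1pr1, the receptor used to leave lymphoid tissue, at 26.7 and 64.3 CPM. Klf2, a transcription factor that maintains S1pr1, was at 195.2 and 375.8 CPM. With the 12 clusters given the same weight in both libraries the list's median was 0.25, though Tcf7, S1pr1 and Klf2 were among the genes that led the naive-like cluster. The ratios of Klf2, Tcf7 and S1pr1 were then 0.01, 0.34 and 0.36.

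Other genes among the highest ratios were Slamf6 (20.9 and 59.2 CPM), Klf3 (7.45 and 22.3 CPM), Ccr6 (11.1 and 22.1 CPM), Klf4 (log2 1.27), Pxdc1 (1.26), Lmo4 (1.01) and Serpine2 (0.98). With equal cluster weights the ratios of Slamf6, Klf3 and Klf4 were 0.37, 0.24 and 0.77, and Serpine2 had 0.53 with equal weight per cell. Gbp2b, which encodes a guanylate-binding protein induced by interferon, stood far from the rest. It had 9 UMIs in WT T cells and 1628 in Tnfr2-/- T cells, or 0.182 CPM (0.0833 to 0.346) and 33.7 CPM (32.1 to 35.3), a log2 ratio of 7.53. The ratio was 10.65 without its 5 richest cells per library, which held 88.9% of the WT UMIs. With so few of the 9 WT UMIs left, that value is not read as a size. Reads of this gene may be shared with closely related members of its family. Ccl3, a chemokine gene, was at 13.8 and 41.7 CPM, but its 5 richest cells held 48.2% of its UMIs in WT and 68.5% in Tnfr2-/-. Without those cells its ratio was 0.88 in place of 1.60, over all cells sorted it was 0.98, and in T cells chosen one by one by their UMIs 2.52. That last choice, a per-cell gate, kept only 2655 WT and 3931 Tnfr2-/- cells, against 5501 and 5976 in the T cell clusters.

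**Figure D1:**
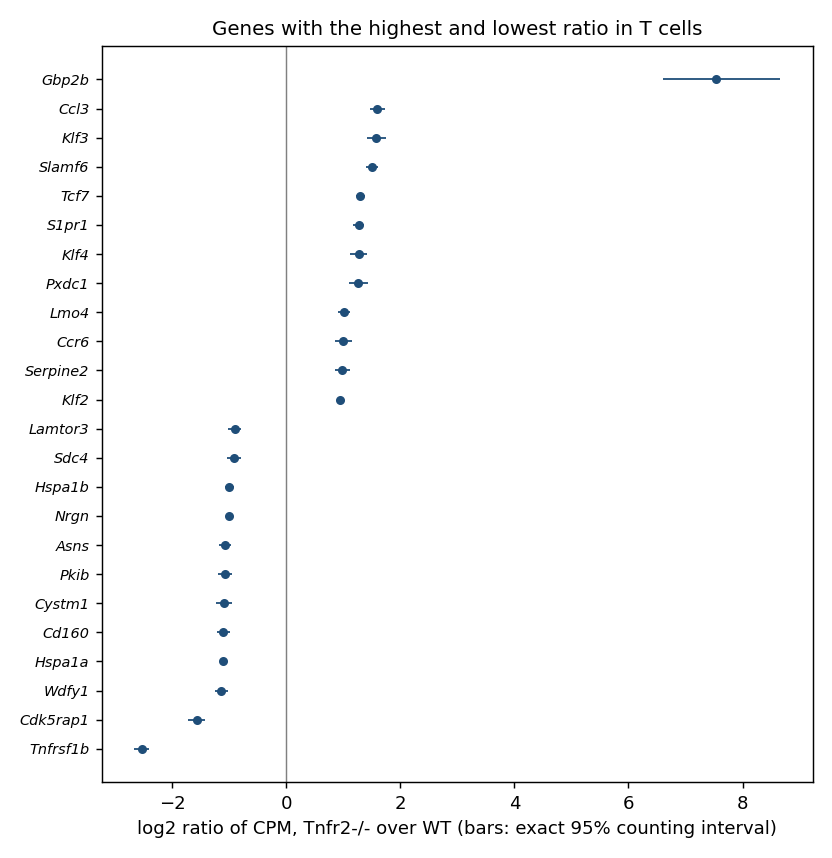
The x axis is the log2 ratio of CPM in T cells, Tnfr2-/- over WT, for the 12 genes with the highest and the 12 with the lowest ratio, and bars are exact 95% counting intervals. Gbp2b lies at 7.53, apart from the other genes, and Tnfrsf1b has the lowest ratio, -2.54.

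At the other end, after Tnfrsf1b, the lowest ratios were those of Cdk5rap1 (31.2 CPM in WT and 10.5 CPM in Tnfr2-/-, log2 -1.57) and Wdfy1 (46.2 and 21.0 CPM, -1.14). The inducible heat shock genes Hspa1a (235.7 and 109 CPM, -1.11) and Hspa1b (96.4 and 48.3 CPM) were also lower in the Tnfr2-/- library. These 2 genes are near-identical copies, so their split is uncertain. Nrgn, the most abundant gene of this group, was at 625.6 and 310.6 CPM (-1.01). Cd160, an inhibitory receptor gene, was at 38.8 and 18.1 CPM, and Asns, encoding asparagine synthetase, at 46.0 and 21.9 CPM. Cystm1 (-1.09), Pkib (-1.07), Sdc4 (-0.92) and Lamtor3 (-0.91) completed the 12. With equal cluster weights the ratios of Nrgn and Cd160 were -0.63 and -0.68. Over all cells sorted those of Pkib and Sdc4 were -0.57 and -0.21.

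Lists of proliferation and energy metabolism genes had medians slightly below those of random lists. All 24 cell cycle genes had a ratio below 0, and none reached 1.5-fold. Their median was -0.23 (random lists -0.07 to 0.06), from -0.04 for Cenpf to -0.38 for Stmn1, with Hmgb2 at 1262 and 1057 CPM. This median was -0.11 with equal cluster weights and -0.39 with equal weight per cell. Of 17 glycolysis genes 12 were below 0 (median -0.15, or -0.088 with equal cluster weights). Hk2, which encodes a hexokinase, had 137 and 89.4 CPM, Gapdh 2562 and 2224 CPM, and Pdk1 a ratio of 0.28. Of 30 nuclear genes for oxidative phosphorylation 25 were below 0 (median -0.13), from 0.18 for Ndufa4 to -0.23 for Cox5a, with Cox8a at 901.1 and 864.1 CPM. The 13 mitochondrially encoded genes did not stand apart (median -0.003). The ribosomal protein genes did, with 70 of 89 above 0 and a median of 0.06.

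Effector cytokines did not share 1 direction. Il17a was at 955.8 CPM in WT and 821.8 CPM in Tnfr2-/- (log2 -0.22), and Ifng at 430 and 364.1 CPM (-0.24). Csf2, which encodes GM-CSF, was at 82.7 and 101.4 CPM (0.29), Tnf at 155.4 and 171.5 CPM (0.14) and Il2 at 29.9 and 39.8 CPM (0.41). Il10, over all T cells, was at 7.05 and 4.80 CPM (-0.55). These ratios moved with the weighting. With equal cluster weights those of Il17a, Ifng and Tbx21 were -0.046, -0.089 and -0.086, and those of Csf2, Tnf and Il10 were 0.56, 0.28 and -1.41. With equal weight per cell Tnf had -0.14, Csf2 0.044, Il17a -0.36 and Ifng -0.55, and in T cells chosen one by one by their UMIs Il10 had 0.11. The ratio of Il2 was 1.02 without its 5 richest cells per library, which held 70.4% and 55.0% of its UMIs, 0.19 with equal weight per cell, 0.79 with equal cluster weights, 0.90 under the stricter cell filter and 2.47 in T cells chosen one by one. In the Tnfr2-/- library 5 cells also held 21.9% of the Ifng UMIs, and without them the ratio of Ifng was -0.50. The list of pathogenic cytokines had 9 of 16 members above 0 and a median of 0.09, at percentile 97.9, and ranged from Ccl3 at 1.60 to Spp1 at -0.53. It no longer stood apart under the stricter cell filter (0.035) or with equal weight per cell (-0.085). Ccl3 was also among the leading genes of the neutrophil-like cluster, and Spp1 among those of the macrophage-like cluster. RNA from such cells therefore stays open as a source of both.

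The Th17 and Th1 programmes and the NF-kappaB and T cell activation lists were within the range of random lists. The Th17 programme (16 genes, median -0.04, mean 0.07) ran from Ccr6, its highest, to Ccl20 at -0.51, with Furin at 1535 and 1266 CPM. With equal weight per cell this list was lower in the Tnfr2-/- library, at -0.20. The Th1 programme (13 genes, median -0.07, mean 0.05) ran from Ly6c2 at 0.98 to Nkg7 at -0.74, with Tbx21 at 25.2 and 21.0 CPM. Of 21 genes of the NF-kappaB pathway, which TNF receptors engage, 20 were within 1.5-fold (median -0.02, mean 0.03), among them Nfkbia at 1626 and 1416 CPM and Nfkb1 at -0.28. Cd83 was the exception, at 7.53 and 13.8 CPM. All 17 T cell activation genes were within 1.5-fold, from Cd28 at 0.33 to Egr2 at -0.17. Inhibitory receptors had a median of 0.08, from Tox at 0.95 to Cd160 at -1.10. The interferon response list had a median of 0.08, from Ifit1bl1 at 0.72 to Mx1 at -0.35, but stood apart as lower with equal cluster weights (-0.14) and as higher under 5 alternatives. These were the stricter cell filter (0.17), totals without ribosomal and mitochondrial genes (0.13), equal weight per cell (0.12), all cells sorted (0.19) and members with at least 1 UMI (0.11). Apoptosis regulators had 0.02, from Bcl2 at 0.44 to Pmaip1 at -0.34, and MHC class I genes -0.08, from Nlrc5 at 0.24 to Psmb9 at -0.25.

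Several other lists were higher in the Tnfr2-/- library. The TNF and TNF receptor superfamily, without Tnfrsf1b, had 15 of 21 members above 0 and a median of 0.13, from Cd27 at 17.4 and 32.7 CPM to Tnfsf10 at 32.7 and 24.1 CPM. It did not stand apart with equal weight per cell or over all cells sorted (both 0.10). Adhesion and migration genes had 14 of 21 above 0 and a median of 0.18. The chemokine receptor Cxcr6 was at 673 and 621.9 CPM, and Itgav at -0.30. The Tfh list had a median of 0.20 over 9 genes, from Slamf6, its highest, to Tox2 at -0.25, and did not stand apart under 4 alternatives (0.089 with equal weight per cell). The Th2 list had 0.53 over 6 genes (0.35 with equal cluster weights), with Areg at 238.4 and 164.4 CPM. The Th2 cytokine Il13 was at 8.52 and 41.6 CPM, and its 5 richest cells held 55.8% and 64.4% of its UMIs. Immediate early and heat shock genes had a median of 0.06 and a mean of -0.10, opposite in sign, from Zfp36 at 0.28 to Hspa1a at -1.11, with Junb at 3144 and 2772 CPM. This list did not stand apart under 4 alternatives, among them equal cluster weights (-0.045). Cytotoxic granule genes did not stand apart (median 0.09) but held members far apart in both directions, Gzmk at 2.96 and 14.3 CPM and Gzma at 165.8 and 63.3 CPM, of which 5 cells held 28.9% and 49.1% of the UMIs.

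**Figure D2:**
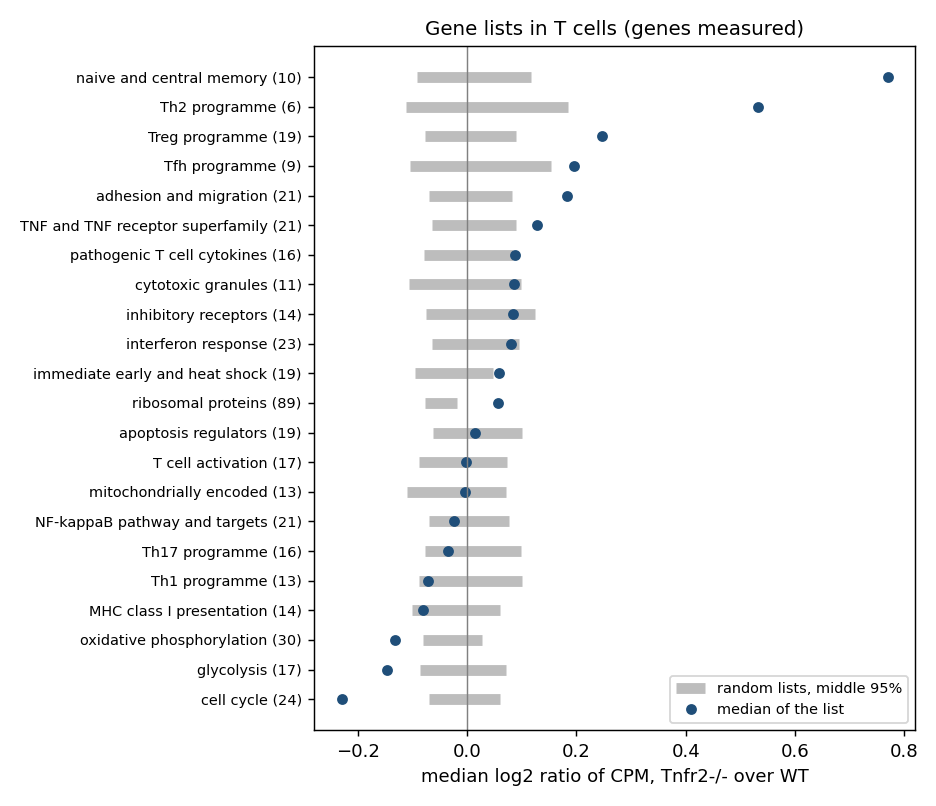
The x axis is the median log2 ratio of CPM, Tnfr2-/- over WT, of each gene list in T cells, with the number of genes measured beside its name, and grey bars are the middle 95% of 10000 matched random lists. Naive and central memory genes lie furthest to the right, at 0.77, and cell cycle genes furthest to the left, at -0.23.

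Markers of other cell types moved with these differences, although the cells were sorted for CD4. CD8 T cell markers were higher in the Tnfr2-/- library's T cells (median 0.31), with Cd8a at 1.56 and 8.25 CPM. Of the 8, Gzma (-1.39) and Nkg7, the most abundant, at 750.7 and 450.2 CPM (-0.74), were lower. Monocyte and macrophage markers were higher too (0.41, or 0.093 and not apart for members with at least 20 CPM), with Apoe at 60.6 and 91.7 CPM, while Lyz2 was lower, 86.1 and 54.7 CPM. Medians were also above the random lists for conventional dendritic cells (0.59), B cells (0.43) and ILC2 (0.47, a list whose measured members are, but for Klrg1, also in the Th2 list). They were below them for plasma cells (-0.26), microglia (-0.28) and plasmacytoid dendritic cells (-0.13), but over all cells sorted the last 3 had 0.20, 0.92 and 1.10. NK cell markers had 0.09 with a mean of -0.20. Haemoglobin, erythroid, mast cell, neutrophil, astrocyte, endothelial, oligodendrocyte, gamma-delta T cell and sex-linked lists had under 3 genes measured. Cd4 itself was at 220.5 and 221.6 CPM.

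Cells with a naive-like or Treg-like profile took larger shares of the T cells in the Tnfr2-/- library. The naive-like cluster held 4.56% of T cells in WT (4.03 to 5.15) and 15.2% in Tnfr2-/- (14.3 to 16.1). Its 10 leading genes also differed among the other T cells (median log2 ratio 0.85), so its size depends partly on their level. When the cells were clustered without the leading genes of any T cell cluster, a choice made after seeing the data, the matching cluster held 4.22% and 13.7%. Treg-like cells made up 4.80% (4.25 to 5.40) and 9.30% (8.58 to 10.1), or 4.84% and 9.05% without those genes. Cycling-like cells in 3 clusters were 17.3% and 12.3%, or 17.2% and 12.7%. Their difference was -4.99 percentage points, and -9.04 under the stricter cell filter. Among them, cluster 14 also had the Treg genes Ikzf2, Klrg1 and Foxp3 among its leading genes and held 1.60% and 0.94%, the opposite order to the Treg-like cells. Cluster 10, unnamed and led by Gzmk and Ccl5, held 2.71% and 7.35%, or 3.78% and 7.85% without those genes. It also had interferon-response genes among its leading genes. A naming condition added after the clusters were seen kept it out of the interferon-responding-like class. Gzmk and Ccl5 are both in the list of CD8 T cell markers, and Ccl5 is also in the Th1 list. Cd8a and Cd8b1 were not among the leading genes of this cluster. Whether it held CD8 T cells was not tested, so its share is not read as one of CD4 T cells. The GM-CSF-producing-like share was 17.3% and 9.67%, or 22.7% and 13.2%, with a difference that turned to 0.991 percentage points higher in Tnfr2-/- at resolution 2. Th17-like cells (11.5% and 10.4%), interferon-responding-like cells (4.73% and 3.01%) and unnamed cluster 6 (13.2% and 5.96%) had no cluster of their own without those genes, so their sizes are not compared. Unnamed cluster 1 held 13.8% and 15.5%, or 22.4% and 26.0% without those genes. Unnamed cluster 4 held 10.2% and 11.5%, or 24.8% and 17.4%, the opposite order, so none is read.

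**Figure D3:**
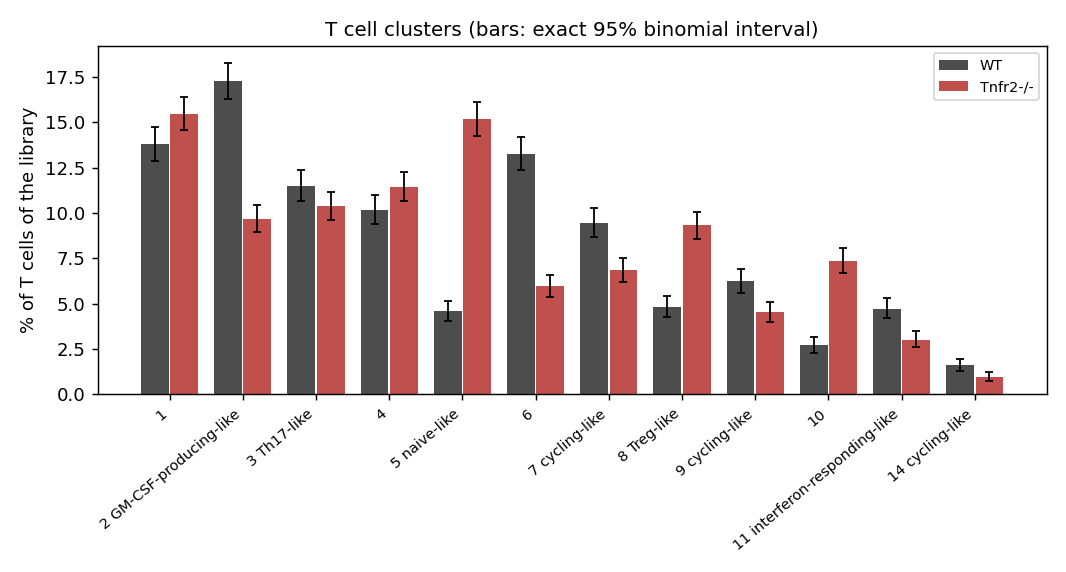
Bars give the percentage of each library's T cells in each of the 12 T cell clusters, dark grey for WT and red for Tnfr2-/-, with exact 95% binomial intervals. Naive-like cells were 4.56% and 15.2% and Treg-like cells 4.80% and 9.30%.

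Counting cells by single genes gave the same order for Foxp3, the Treg transcription factor. After thinning, 2.90% of WT T cells (2.47 to 3.39) and 5.66% of Tnfr2-/- T cells (5.08 to 6.29) had a Foxp3 UMI, against 6.51% and 9.87% without thinning. Macrophage-like cells, which should lack the gene, had 0% and 0.405%, at median depths of 13951 and 13127 UMIs before thinning. Foxp3 was at 20.4 and 38.2 CPM over all T cells (log2 0.91, or 0.59 with equal cluster weights). The Treg programme list had 14 of 19 members above 0 and a median of 0.25, from Lrrc32 at 0.99 to Il10 at -0.55, with Capg at 1009 and 820 CPM.

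Cells with an Il17a or Ifng UMI were fewer in the Tnfr2-/- library of these sorted cells. After thinning, Il17a was seen in 29.0% of WT and 21.6% of Tnfr2-/- T cells (44.2% and 33.1% unthinned), beside 8.13% and 3.64% of macrophage-like cells. Ifng was seen in 29.3% and 18.6% (49.3% and 33.2% unthinned), beside 5% and 1.22%. These background shares, from 160 and 247 cells, were also lower in the Tnfr2-/- library. For Il17a the difference was -7.37 percentage points (-8.98 to -5.75) beside a WT background of at most 13.5%, so free RNA stays open. For Ifng it was -10.7 points (-12.3 to -9.12) beside a WT background of 5%, at most 9.61%, so the measured background is smaller than the difference and free RNA stays open for part of it. Mki67, a proliferation marker, was seen in 12.2% and 9.32% (23.6% and 18.6% unthinned), with 0% and 3.45% in only 10 and 29 neutrophil-like cells (median depths 1993 and 2495 UMIs), which allow up to 30.9% and 17.8% and so set no background. Csf2 (7.56% and 7.12%, unthinned 19.0% and 15.3%) and Tnf (17.3% and 14.4%, unthinned 38.7% and 31.7%) went against their CPM, and no order is read from them. Tbx21 was seen in 4.46% and 4.16% (unthinned 17.4% and 13.3%). Il2 was seen in 0.943% and 1.39% (unthinned 2.62% and 3.23%) and Il10 in 0.924% and 0.757% (unthinned 1.93% and 1.79%). Macrophage-like cells had at most 0.405% for Csf2, Tbx21 and Il2. For Il2 their 0% allows up to 2.28% in WT and 1.48% in Tnfr2-/-, above the T cell shares, and sets no background. For Il10 the neutrophil-like cells had 0%, which allows up to 30.9% and 11.9% and sets no background. No class lacking Tnf was available.

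Within Treg-like cells (264 in WT with 1905015 UMIs, 556 in Tnfr2-/- with 3337731 UMIs), Foxp3 was higher and the anti-inflammatory cytokine gene Il10 lower in the Tnfr2-/- library. Foxp3 was at log2 0.59 (0.44 to 0.74), with a UMI in 74.6% of these cells in WT and 73.6% in Tnfr2-/-. Foxp3 and other genes of the Treg list led this cluster and gave it its name. Their levels inside it therefore depend partly on which cells it took in. Il10 was at 132.3 CPM in WT and 38.1 CPM in Tnfr2-/-, a log2 ratio of -1.80 (-2.12 to -1.48). Among all T cells with a Foxp3 UMI, whatever their cluster, the ratio of Il10 was -0.92. The checkpoint receptor gene Lag3 (-1.40), Nrgn (-1.49) and Camk2n1 (-1.39) were the lowest besides Il10 and Tnfrsf1b (-2.88). Slamf6 (1.20) and Gbp2b (3.91) were among the highest, the latter on 8 WT UMIs that all lay in 5 cells. In T cells with a Foxp3 UMI, Lag3 had -0.36, Nrgn -0.45, Camk2n1 -0.59 and Slamf6 0.72. Ifng was at -1.26 in the Treg-like cluster and at 0.90 in those cells. Within the Treg-like cluster 5 cells held 44.8% of the Nrgn UMIs in WT and 53.8% in Tnfr2-/-. For Lag3 they held 24.9% and 32.7%, and for Ifng 54.3% and 41.7%. Nrgn, Lag3 and Ifng were also among the leading genes of the GM-CSF-producing-like cluster, so a change within Treg cells is not shown for them. Il2 and Il22 also ranked among the highest, but 5 cells held 98.1% and 94.6% of their Tnfr2-/- UMIs. Ttr, a choroid plexus gene, had a ratio of 1.26, with UMIs in 26.9% and 43.7% of these cells, and free RNA stays open as its source. Naive and central memory genes were higher (median 0.48), as were the Treg (0.14), Th2 (0.61), Tfh (0.43) and immediate early (0.14) lists. Markers of other cell types moved with them: ILC2 (0.76), monocyte and macrophage (0.50) and conventional dendritic cell (0.48) markers were higher, and CD8 T cell (-0.40) and plasmacytoid dendritic cell (-0.57) markers lower. Cell cycle (-0.31), cytotoxic granule (-0.46), glycolysis (-0.22), oxidative phosphorylation (-0.21) and apoptosis (-0.16) genes were lower.

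In the other T cells (5237 and 5420), Il10 had a ratio of 0.21 with an interval that included 0 (-0.21 to 0.62), at 2.02 and 2.33 CPM. Slamf6 (1.47), Tcf7 (1.32), S1pr1 (1.26), Lmo4 (1.04) and Klf2 (0.95) had the highest ratios. Tnfrsf1b (-2.54), Hspa1a (-1.10), Hspa1b, Nrgn (-0.97) and Ckb, encoding creatine kinase B (-0.80), had the lowest. Naive and central memory genes (0.76) and cell cycle genes (-0.20) stood apart there as well, as did the Th2 (0.31), Tfh (0.20), adhesion (0.18), TNF superfamily (0.098), glycolysis (-0.15) and oxidative phosphorylation (-0.12) lists. The Treg programme did not (0.054). Markers of conventional dendritic cells (0.58), B cells (0.41), monocytes and macrophages (0.38), CD8 T cells (0.36) and ILC2 (0.29) were higher there, and those of plasma cells (-0.25), microglia (-0.26) and plasmacytoid dendritic cells (-0.16) lower. Whether the difference between the libraries itself differed between Treg-like and other T cells was not tested.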

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

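The cells outside the T cell clusters were not part of the comparisons above, and some of their shares were higher in the Tnfr2-/- library than in the WT library by more than the counting intervals. Both sorts were for CD4. Plasmacytoid dendritic cell-like cells were 0.225% of clustered WT cells (13 cells, interval 0.12 to 0.384) and 1.43% of Tnfr2-/- cells (94 cells, 1.16 to 1.75). A Cd4 UMI was present in 76.9% and 67.0% of them, beside 5% and 4.65% of neutrophil-like and 13.3% and 22.6% of macrophage-like cells. This does not tell which cells carried CD4 protein at the sort. B cell-like cells numbered 0 of 5787 in WT, which allows a share of up to 0.0637% (the exact binomial limit), and 17 in Tnfr2-/- (0.259%). Monocyte and macrophage-like cells were 2.85% and 3.91%, conventional dendritic cell-like cells 1.31% and 2.18%, and gamma-delta T cell-like cells 0.121% and 0.411%. With 1 library per group, a cluster mostly of 1 library may be a feature of that library.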

How the results depend on the processing

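The clustering without leading genes and the removal of the 5 richest cells per library were chosen after seeing the data, and the other alternatives before. Within their counting intervals stayed 243 of 350 gene ratios in T cells, 91 of 116 within classes, 27 of 40 shares with a UMI and 17 of 30 class shares, while 273 of 306 list calls were the same. Ratios that reversed were Tnf with equal cell weight (-0.14), Il10 in T cells taken by a per-cell gate (0.11), and in Treg-like cells Il17a (0.12) and Ifng (0.90) when classed by a Foxp3 UMI, and Il17a without the richest cells (0.024). The per-cell gate kept 2655 WT and 3931 Tnfr2-/- cells, fewer than the T cell clusters held. Lists that reversed were the microglia markers (0.92 over all cells, 0.41 at 1 UMI) and plasmacytoid dendritic cell markers (1.10 over all cells). No longer apart were pathogenic cytokines under the stricter filter (0.035) or equal cell weight (-0.085), and the Tfh list with no filter (0.14), doublets kept (0.13), equal cell weight (0.089) or all cells (0.16). The same held for the TNF superfamily with equal cell weight (0.10) or all cells (0.10). It also held for immediate early genes with no filter (0.040), doublets kept (0.044), equal cell weight (0.020) or equal composition (-0.045). In percentage points, Tnfr2-/- minus WT, the GM-CSF-producing-like share was -13.2 at resolution 0.5, 0.991 at resolution 2, -4.59 with centred genes, -0.818 with doublets kept and -9.54 without leading genes. The Th17-like share was 0.912 with centred genes, -10.8 with doublets kept and 0.085 under the stricter filter. Under that filter the cycling-like share was -9.04 and the interferon-responding-like share -0.725. The naive-like share was 9.47 at resolution 2, 9.29 with centred genes and 9.47 without leading genes. The cause of these moves was not tested. No naive-like or Th17-like cluster could be named at resolution 0.5, no Th17-like cluster at resolution 2 and no GM-CSF-producing-like cluster under the stricter filter, and Th17-like and interferon-responding-like cells had no cluster of their own without leading genes. No paired analysis was possible because each group had 1 library. A floor of 3 UMIs, or 0.0607 CPM in WT and 0.062 CPM in Tnfr2-/-, was set as an approximate limit for a count of 0. The exact Poisson interval used for CPM allows slightly more.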

Other observations

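The tests of single genes near Tnfrsf1b and near Gbp2b, of the naive-like cluster left out and all 3 tests of Il10 were chosen after the result was seen, and the others before. Along the chromosome next to Tnfrsf1b, zinc finger genes differed most, singled out here after their values were seen. Zfp990 (chromosome 4, from 145510759) had 3 UMIs in WT and 456 in Tnfr2-/- T cells, 0.0607 and 9.43 CPM (log2 7.28, 5.72 to 9.56). Zfp992 was at 2.23 and 11.6 CPM (2.38) and Zfp984 at 7.31 and 3.41 CPM (-1.10). These genes belong to a family of close copies, so their counts are uncertain. Of the 42 genes measured within 5 Mb of Tnfrsf1b, 4 differed by 1.5-fold, as many as the upper limit of 10000 matched random lists. Around Gbp2b on chromosome 3, the related Gbp3 was at 18.8 and 35.3 CPM and Pdlim5 at 19.2 and 11.2 CPM.

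One pattern is that single genes such as Gbp2b and Cdk5rap1 differed whatever the cluster mix (log2 6.90 and -1.52 with equal cluster weights). The tables argue against mice of different sex, since the ratio of Xist was -0.040 (1006 and 978 CPM) and Y-linked genes had 2 and 5 UMIs in all. Variants of another strain carried along with the targeted Tnfrsf1b did not pass the test set in advance, a median absolute log2 ratio of 0.17 over 42 genes (percentile 96.1, limit 0.17), but that bound, judged after the value was seen, was a poor one, because such a median does not show a few altered genes, and the 4 genes at 1.5-fold keep this open. For segments elsewhere, the 23 genes with 2-fold ratios held 2 pairs within 5 Mb (random lists up to 5, percentile 69.1). That count was inside the random range but cannot decide the question, because a segment that alters a single gene adds no pair. Wdfy1 and Serpine2, neighbours on chromosome 1 (to 79776143 and from 79794197), formed no pair because Serpine2 was at 1.98-fold. Around Gbp2b 5 of 30 genes differed by 1.5-fold (random lists up to 2), 3 of them outside the Gbp family. The median absolute log2 ratio of that window, 0.14, was inside the random range (percentile 91.6). A segment of another strain's genome on chromosome 3 stays possible for Gbp2b, Lmo4 and Lamtor3, beside the loss of TNFR2 itself, which was not tested. Lmo4 and Lamtor3 were seen before the window was chosen, so the count of 5 partly restates their ratios. Gbp3 and Gbp7, also counted, are related to Gbp2b. Only Pdlim5 is left besides these, so the count cannot decide the question. Lmo4 was also among the leading genes of the naive-like cluster, so its ratio may come partly from the mix of cells.

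Another pattern is the higher level of naive and central memory genes in the Tnfr2-/- library. The tables argue against lower depth per cell, since the list's median was 0.49 with 5 bands of UMIs per cell weighted equally, above all random lists. With the naive-like cluster left out the median was 0.61, so the cells placed in that cluster were not its whole source. The list's median was 0.25 with all 12 clusters weighted equally and 0.09 within the naive-like cluster. All clusters were built partly from the same genes, and naive-like cells may lie in other clusters. None of these values therefore tells how much of the difference lay in the mix of cells. Loss of TNFR2, a different course of disease in the sampled mice and a difference between the libraries stay open and untested.

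The last pattern is the lower Il10 in Treg-like cells of the Tnfr2-/- library. The tables argue against a few cells as its source, since the ratio was -1.88 (-2.30 to -1.48) without the 5 richest cells per library. They argue against depth, as 12.6% of WT (8.78 to 17.3) and 3.84% of Tnfr2-/- Treg-like cells (2.36 to 5.87) had an Il10 UMI after thinning. Among Treg-like cells with a Foxp3 UMI the ratio was -1.56 (-1.91 to -1.21), which argues against other cells in the cluster, although it was -0.92 over all T cells with a Foxp3 UMI. Loss of TNFR2 and any other difference between the mice or libraries stay open, since no test here separates them with 1 library per genotype.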
